A study of Mus musculus with 4 samples.

How the data were processed

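Single cells were measured from lower incisor germs of C57BL/6 mouse embryos, in 4 libraries with 1 library per group. The groups were wild type at embryonic day (E) 14.5, E15.5 and E16.5 and a Six1 knockout at E15.5. Per the labels, the tissue was dissociated with trypsin, cells were captured in micro-wells with a GEXSCOPE kit, and the libraries were sequenced on an Illumina NovaSeq instrument. The submitters' processing notes name STAR without a version, featureCounts 2.0.1 and the mouse build GRCm38 (mm10). Each deposited matrix holds raw counts per gene and cell barcode, without normalisation, and the lowest total of any deposited barcode was 500 counts. The labels do not state whether a count is a read or a distinct molecule, so the values are called counts. Of the 53715 deposited gene identifiers, 53620 matched GENCODE release M21, which gave coordinates on GRCm38, transcript lengths and GC contents.

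Barcodes with at least 500 genes and at most 20% mitochondrial counts were kept. Doublets were scored with Scrublet in each library at an expected rate of 5%. Where the automatic threshold called fewer than 0.5% of the barcodes, the 5% highest scores were removed, which applied to wild type E14.5 (1 automatic call) and wild type E15.5 (0 calls). The automatic calls were used in wild type E16.5 (194, 1.56%) and in the knockout (259, 2.33%). In order of wild type E14.5, E15.5, E16.5 and knockout, 13028, 18064, 13175 and 13108 deposited barcodes became 11725, 15786, 12224 and 10858 cells. No correction for free RNA and no alignment between libraries was applied in the main values.

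Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with all genes of the Dlx and Six1 families left out, and values were scaled with a limit of 10 standard deviations. Clusters came from 30 principal components, 20 nearest neighbours and the Leiden algorithm at resolution 1.0. The 36 clusters were given classes from marker lists that contained no gene of either family. A cluster took a class other than epithelial or mesenchymal when at least 3 of that class's markers stood among its 20 leading genes by fold over all other cells. The remaining clusters were called epithelial-like or mesenchymal-like by the higher mean marker score. Leading genes were detected in at least 10% of the cells of the cluster and ranked with a pseudocount of 5 CPM. This naming rule was chosen after the clusters had been seen. A mesenchymal-like cluster was called papilla-like or follicle-like when at least 3 markers of that tissue were among its 50 leading genes, and cluster 5, with 3 markers of each, was left unnamed. In a check against cells of other classes, the 10 leading genes held more markers of the cluster's own class than of any other except in cluster 34, which was left without a class, but against all other cells the epithelial-like clusters 12, 23, 25 and 27 were led by more markers of another class.

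Counts were summed over the cells of a class in each library and divided by the class total, in the usual scaling of CPM, since cells of 1 library are not replicates. Log2 ratios were formed after adding 0.5 counts to both sums. Intervals are 95% limits for counting error only, exact Poisson for CPM and exact binomial (Clopper-Pearson) for shares and for ratios of counts. Where a library held 0 counts, a limit of 3 counts was used and the fold is given as a bound. With 1 library per group no test between groups and no replicate check was possible, so no p-value is given and a difference can belong to the group or to the library.

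The comparisons, the named-gene rule, 21 gene lists and most alternatives were fixed before the data were examined. The rule named the 10 genes with the highest and the 10 with the lowest log2 ratio among genes with at least 100 counts in the higher sum and an absolute log2 ratio of at least 1. For the knockout its value also had to lie outside those of all 3 wild type libraries, and for stage the E15.5 value had to lie between the other values. Six1, mitochondrial, ribosomal protein, haemoglobin and sex-linked genes and unnamed gene models were left out of this ranking. Genes whose CPM in another class exceeded 10 times that of the class compared were left out as well. A list was summarised by the median log2 ratio of members with at least 20 counts, and by its percentile among 10000 random lists matched in 10 bins of expression. The lists were the Dlx family, Eya-Dach network with Six2, Six4 and Six5, tooth transcription factors, distal jaw patterning, Hedgehog, Wnt, BMP and TGF-beta, FGF and Notch components, enamel knot, ameloblast and enamel matrix, odontoblast and bone matrix, dental epithelial stem cell, fibrillar collagen and matrix, S phase, G2 and M phase, p53 and apoptosis, immediate early response, hypoxia and glycolysis, haemoglobin, and sex-linked genes. The title of the series names Dlx1, Dlx2 and Dlx5, so that list is not independent of the study. Bapx1, Snorc and Lect1 were absent under these symbols.

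The ratio, list and trend steps were tested on simulated counts, with 200 changed genes planted among 53715. All libraries were drawn with Poisson error from the mesenchymal-like profile of wild type E15.5, each at its own total. Differences between libraries beyond those planted were not simulated, so the check covers counting error only. None of the 11105 unchanged genes with the minimum count met the size rule (0 genes). The log2 ratio lay within 0.25 of the truth for 67 of 67 genes planted at 2-fold, 67 of 67 at 4-fold and 62 of 66 at 8-fold, and 40.3% of the 2-fold genes met the rule. A planted list of 15 genes lay at percentile 0, and 9 of 200 random lists lay outside the 2.5th to 97.5th percentile. Removing a planted GC trend across 10881 genes took Spearman's rho from -0.874 to -0.0521 and left 195 of 199 planted genes within 0.25 of the truth.

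Alternatives covered other filters, doublet rules, Leiden resolutions of 0.5 and 2.0, components centred per library, TMM factors, median-of-ratios size factors, means over cells, cells thinned to 2000 counts, and the mean of the 3 wild type libraries as reference. Further alternatives were chosen after the data had been seen: clusters shared by both E15.5 libraries (at least 50 cells in each, equal weights), removal of the trend on GC content and length, subtraction of the change in endothelial-like and immune-like cells, the 5% highest doublet scores removed everywhere, and leaving out clusters of wild type E15.5 alone or the 4 epithelial-like clusters above. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and limma 3.58.1.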

Results

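Gene counts of single cells from the mouse lower incisor germ, the embryonic rudiment of the front tooth, were compared between 3 wild type stages and a knockout of Six1. Six1 encodes a homeodomain transcription factor, and the title of the series states that it acts on lower incisor development through Dlx1, Dlx2 and Dlx5, which encode homeodomain factors of jaw and tooth. Each of the groups wild type E14.5, wild type E15.5, wild type E16.5 and Six1 knockout E15.5 was 1 library, so no value below has a replicate. In that order the libraries held 13028, 18064, 13175 and 13108 barcodes, with 105032824, 99930722, 112681417 and 85782821 counts in total. The median barcode held 6143.5, 4005, 7129 and 5447 counts and 2526, 1944, 2608 and 2164 genes. After the filters 11725, 15786, 12224 and 10858 cells remained.

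Six1 was nearly absent from the knockout library. Six1 (ENSMUSG00000051367, GRCm38 chromosome 12, 73040015 to 73053887) measured 27.6 CPM in mesenchymal-like cells of wild type E14.5 (95% interval 26.2 to 29.0), 38.1 at E15.5 (36 to 40.3) and 20.8 at E16.5 (19.3 to 22.4), against 0.597 in the knockout (0.393 to 0.868). The knockout value was 62.7-fold below wild type E15.5, with a log2 ratio of -5.97 (-6.60 to -5.45), and rested on 27 counts, 15 of them in cluster 0. In epithelial-like cells Six1 was lower throughout, at 3.0, 5.21 and 3.76 CPM in the wild type stages, and 0 counts were found in the knockout, at least 48.8-fold lower than wild type E15.5. Six1 was counted in 12.4% of mesenchymal-like cells of wild type E15.5 (median depth 3256 counts) and in 0.340% of those of the knockout (median depth 5437). Endothelial-like cells, which should lack the gene, held a Six1 count in 0.456% of 439 cells in wild type E15.5 (median depth 7860) and in 0 of 173 in the knockout, which allows up to 1.73%. Erythroid cells, which should lack it too, held one in 2.68% of 634 cells (median depth 1442.5) and in 0 of 494. Epithelial-like cells of wild type E15.5 held one in 3.31% (median depth 5925.5), and among cells deep enough to be thinned to 2000 counts in 1.20% against 2.63% in erythroid cells, so Six1 in the epithelium was not above the background of every class. Within the wild type mesenchyme of E15.5, Six1 reached 88.9 CPM in cluster 5 and 59.1 in the papilla-like cluster 9, and it measured 19.5 in cluster 15.

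Mesenchymal-like and epithelial-like cells made up most of every library, in shares that shifted with stage. Mesenchymal-like cells were 65.8% of cells at E14.5 (64.9 to 66.7), 50.1% at E15.5 (49.3 to 50.9) and 41.4% at E16.5 (40.6 to 42.3) in wild type, and 64.9% in the knockout (64.0 to 65.8). Epithelial-like cells were 17.8% (17.1 to 18.5), 39.1% (38.3 to 39.8), 43.5% (42.6 to 44.4) and 26.9% (26.1 to 27.8) in the same order. Osteogenic cells, expressing bone matrix genes, numbered 1227 in wild type E16.5 and 3, 0 and 0 in wild type E14.5, wild type E15.5 and the knockout. Chondrogenic cells numbered 1000 in wild type E14.5 and at most 10 in any other library. Endothelial-like cells numbered 246, 439, 243 and 173, immune-like cells 129, 262, 57 and 125, and erythroid cells 403, 634, 258 and 494. Muscle cells numbered 51, 69, 0 and 3, glial cells 71, 128, 8 and 25, and mural cells 15, 157, 44 and 8. Dissection and dissociation can set such shares, and 1 library per group cannot separate them from stage or genotype.

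Papilla-like clusters, named from genes of the dental papilla that gives rise to the pulp and odontoblasts, held 14.49% of mesenchymal-like cells at E14.5 (13.7 to 15.3), 14.2% at E15.5 (13.4 to 15) and 76.8% at E16.5 (75.6 to 78.0). In the knockout they held 1.96% (1.65 to 2.31), 138 cells, of which 135 were in cluster 9. Follicle-like clusters, named from genes of the dental follicle around the germ, held 12.7%, 14.4% and 21.5% in the wild type stages and 57.6% in the knockout (56.4 to 58.7). Of the 4059 follicle-like knockout cells, 4048 lay in cluster 0, which held 93 cells of wild type E15.5 and 0 of wild type E16.5, while the wild type follicle-like cells lay mainly in cluster 11 (834 at E14.5 and 1010 at E15.5) and cluster 21 (1050 at E16.5). Cluster 15, which held 1418 cells of wild type E15.5 and 1 of the knockout, expressed papilla genes but had too few markers among its leading genes to be named papilla-like. Fgf3 and Fgf10, papilla markers used in the naming, were themselves lower in the knockout, so a loss of marker expression and a loss of cells give the same change in these shares. At a Leiden resolution of 0.5 the follicle-like order turned, with 13.0% in the knockout and 30.3% in wild type E15.5, while papilla-like cells stayed lowest in the knockout, at 0.0422% against 7.91%. Papilla-like shares were then 0.0906% at E14.5 and 31.4% at E16.5. Follicle-like shares were 45.8% and 1.01% at these stages, so they fell with stage rather than rose. With 1 library per group, a cluster mostly of 1 library may be that library.

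**Figure D1:**
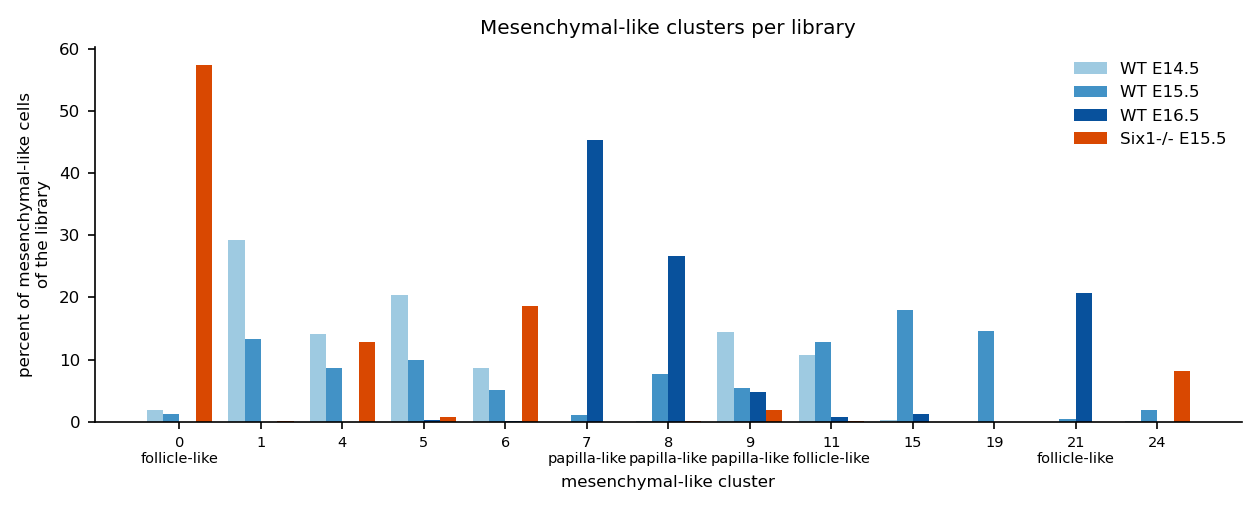
Share of each library's mesenchymal-like cells (vertical axis, percent) in each of the 13 mesenchymal-like clusters (horizontal axis), with 1 bar per library and papilla-like and follicle-like clusters named under the axis. Cluster 0 held 4048 of the 7049 mesenchymal-like knockout cells, and clusters 7 and 8 held 2294 and 1352 of the 5066 of wild type E16.5.

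The comparison of the knockout with wild type E15.5 asked which genes depend on Six1, first in mesenchymal-like cells. Dlx1 and Dlx2 were far lower in the knockout, and Dlx5 was moderately lower. Dlx1 (ENSMUSG00000041911, chromosome 2, 71528113 to 71533981) measured 67.8 CPM in wild type E15.5 and 3.18 in the knockout, a 21.2-fold difference with a log2 ratio of -4.41 (-4.67 to -4.17). Dlx2 (ENSMUSG00000023391, chromosome 2, 71543408 to 71546754) measured 65.2 and 7.71 CPM, a log2 ratio of -3.08 (-3.25 to -2.92), and Dlx5 (ENSMUSG00000029755, chromosome 6, 6877805 to 6882085) 94.3 and 54.2 CPM, a log2 ratio of -0.80 (-0.87 to -0.72). The knockout values of these 3 genes also lay below wild type E14.5, where Dlx1 measured 5.24, Dlx2 56.5 and Dlx5 89.1 CPM. Dlx3 (-2.51), Dlx4 (-2.58) and Dlx6 (-0.70) were lower as well, so that all 6 Dlx genes were below 0 under each scaling tried, with a list median of -2.55 at percentile 0 of random lists. Dlx1 was counted in 15.8% of mesenchymal-like cells of wild type E15.5 and 1.55% of those of the knockout, and Dlx2 in 16.3% and 2.34%. In endothelial-like cells, which should lack these genes, Dlx1 was counted in 2.05% of wild type and 1.16% of knockout cells and Dlx2 in 7.97% and 0.578%, at median depths of 7860 and 10615 counts. Erythroid cells, which should also lack them, held Dlx1 in 9.62% and 11.5% and Dlx2 in 20.3% and 7.69%. Their median depths were 1442.5 and 1655. The knockout mesenchyme thus lay between the backgrounds of these classes for both genes. The wild type mesenchyme did so for Dlx2, while its Dlx1 lay above both backgrounds. Among wild type E15.5 cells thinned to equal depth, mesenchymal-like and erythroid cells held Dlx1 in 10.3% and 10.0% and Dlx2 in 10.3% and 23.7%. These shares therefore did not set the wild type mesenchyme apart from every background either.

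**Figure D2:**
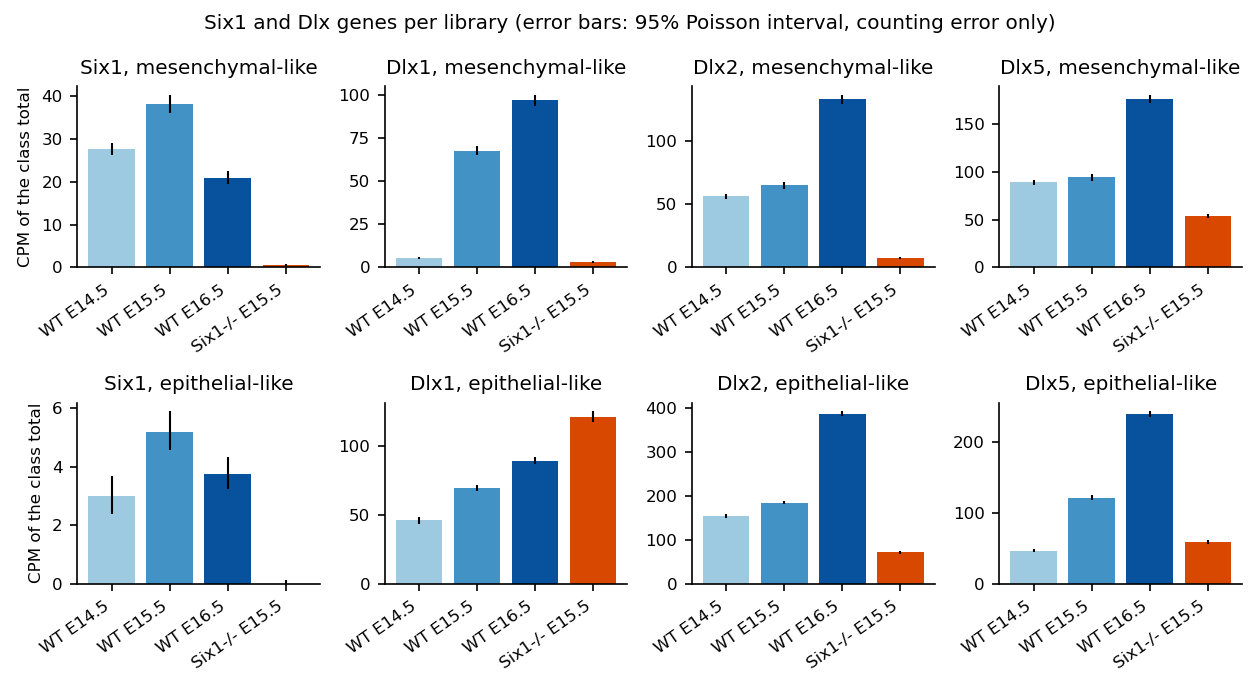
Level of Six1, Dlx1, Dlx2 and Dlx5 (vertical axes, CPM of the class total) in mesenchymal-like cells (upper panels) and epithelial-like cells (lower panels) of the 4 libraries, with 95% Poisson intervals as error bars. In mesenchymal-like cells the knockout was lowest for all 4 genes, and in epithelial-like cells Dlx1 was highest in the knockout, at 121.5 CPM.

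Where the Dlx counts lay differed between clusters. In wild type E15.5, cluster 15 alone gave 1438 of the 2247 mesenchymal-like Dlx1 counts, at 384.5 CPM, and this cluster was nearly empty in the knockout. In cluster 9, the papilla-like cluster shared by both E15.5 libraries, Dlx1 measured 18.8 CPM in wild type (13.9 to 24.9) and 37.9 in the knockout (29.1 to 48.6), and Dlx2 52.6 (44.2 to 62.2) and 128.4 (111.6 to 147.0). Dlx5 in that cluster measured 78.3 CPM in wild type and 133.3 in the knockout, while Six1 went from 59.1 CPM to 0 counts. In the shared clusters 0, 4, 6 and 24, wild type Dlx1 lay between 3.28 and 14.4 CPM and Dlx2 between 7.99 and 26.3 CPM, close to the 9.31 (5.76 to 14.2) and 21.3 (15.7 to 28.2) of immune-like cells, and the knockout values were lower in all 4, with overlapping intervals for Dlx1 in clusters 0 and 4 and for Dlx2 in cluster 24. Averaged over the 5 shared clusters with equal weights, the log2 ratio was -1.40 for Dlx1, -1.86 for Dlx2 and -0.05 for Dlx5. Wild type E15.5 levels per cluster, weighted by the knockout's cluster composition, gave 6.21 CPM for Dlx1, 19.8 for Dlx2 and 58.7 for Dlx5.

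**Figure D3:**
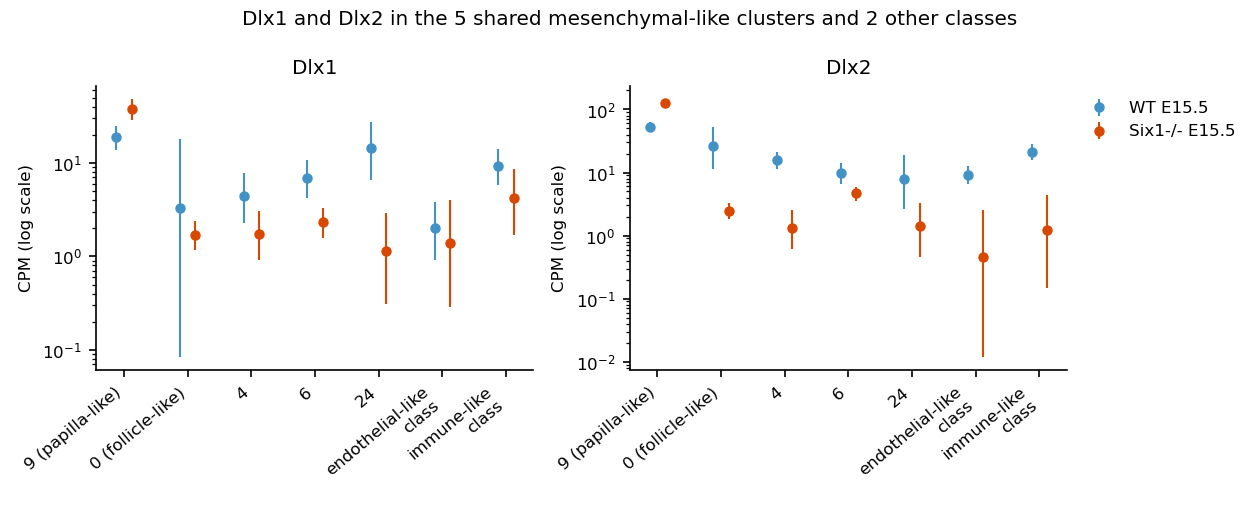
Dlx1 and Dlx2 (vertical axes, CPM on a log scale) in wild type E15.5 and the knockout, in the 5 shared mesenchymal-like clusters and in endothelial-like and immune-like cells (horizontal axes), with 95% Poisson intervals. In cluster 9 the knockout was higher for both genes (37.9 against 18.8 CPM for Dlx1), and in clusters 0, 4, 6 and 24 it was lower, at 1.13 to 2.33 CPM for Dlx1.

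The genes named as highest in the knockout mesenchyme were led by Cilp, an extracellular matrix protein of cartilage, at a log2 ratio of 5.20 (3.99 to 7.26), and by Lingo2 at 4.11, Rasef at 3.77 and Rn7sk, a small nuclear RNA, at 3.65. Tbx22, a T-box factor of palate and jaw mesenchyme, was at 3.53, Robo3 at 3.47, Tnn, the matrix protein tenascin-W, at 3.42 (17.5 against 187.0 CPM), Pirt at 3.37, Fam186a at 3.25 and Calca, the calcitonin gene, at 3.23. Rn7sk was higher in endothelial-like cells too, by 3.53, and Pirt stood at -0.0039 over the shared clusters. Among the lowest, Zic1 was at least 371-fold lower (24.6 CPM against 0 counts), Hoxd8 at least 245-fold, Zic3 at least 179-fold, Hoxa2 at least 65.5-fold, Hoxd3os1 at least 57.3-fold and Haglr at least 46.0-fold. Sfrp5, a secreted Wnt inhibitor, was at -9.37 (138.9 against 0.199 CPM), and Hmx1, with 171 counts against 1, at -7.29 (-13.18 to -5.37). These 8 genes had at least 94.8% of their wild type counts in cluster 19, whose 1150 cells all came from wild type E15.5 and whose leading genes included Dpt and Tbx15, expressed in skin dermis, so a difference in the tissue taken and the loss of Six1 give the same folds. Ajap1 at -6.10 (-8.15 to -4.89) and Ecel1 at -6.00 (-8.51 to -4.65, 3 counts in the knockout) had 55.1% and 74.4% of theirs in cluster 15.

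Tooth patterning lists were lower in the knockout mesenchyme. Of 24 tooth transcription factors, 9 were at or below -1 and 2 at or above 1, with a median of -0.62 (percentile 0.05), including Sp6, an epithelial tooth factor, at -4.69, the homeobox gene Msx2 at -3.58 (75.4 against 6.28 CPM) and Sall1 at -3.09. The 13 distal jaw patterning genes had a median of -0.91 (percentile 0.47), 6 at or below -1, among them Nr2f2 at -3.51 and Gsc at -1.06. Against the mean of the 3 wild type libraries that median was -0.15 and Gsc was at 0.37, and without the trend on GC content and length the median was -0.10 (percentile 27.3). Hedgehog components were below 0 in 11 of 12 members (median -1.08, percentile 0.02), with the ligand Shh at -3.67, the antagonist Hhip at -2.26, the co-receptor Gas1 at -1.91 and Ptch2 at -1.65. Notch components were below 0 in 12 of 13 (median -0.98, percentile 0.50), with the targets Nrarp at -3.23, Hey2 at -2.21 and Heyl at -1.95. Enamel knot genes, of the epithelial signalling centre, had 7 of 11 at or below -1 (median -1.78, percentile 0), such as Wnt10a at -2.15. Of 5 ameloblast and enamel genes 4 were at or below -1 (median -3.11, percentile 0), with ameloblastin (Ambn) at -1.83 and Odam at 1.20. Markers of epithelium fell in these mesenchymal-like cells as well, with Krt14 at 83.7 against 34.2 CPM, Krt15 at -3.76 and Epcam at -2.77.

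Signalling lists with mixed members included Wnt (median -0.19, 10 of 28 at or below -1 and 4 at or above 1), where the inhibitors Sfrp2 at -3.52 and Dkk1 at -3.15 and the ligand Wnt6 at -3.13 were lower. After subtraction of the change in endothelial-like and immune-like cells, Sfrp2 stood at 0.22. BMP and TGF-beta components had a median of -0.14, with 6 of 21 at or below -1 and 3 at or above 1, from Fst, the activin antagonist, at -4.12 to Serpine1 at 2.03. FGF components were below 0 in 14 of 16 members (median -0.35, percentile 6.16), with the mesenchymal ligands Fgf10 at -3.001 (38.1 against 4.75 CPM) and Fgf3 at -2.30 and the feedback inhibitors Spry2 at -2.60 and Spry1 at -1.86. The Eya-Dach network had a median of 0.01 over 9 members, with Eya1, a phosphatase and cofactor of Six1, at 2.17 (13.0 against 58.6 CPM), Six4, a relative of Six1, at 1.63 and Dach1 at -2.07. Odontoblast and bone matrix genes were above 0 in 8 of 11 members (median 0.41, percentile 99.9), with Ibsp at 1.27, Ifitm5 at 1.20, Sp7, a bone transcription factor, at 1.16 and Spp1 at -1.55.

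Of the remaining lists in the knockout mesenchyme, only immediate early genes lay in the outer 2.5% of random lists. Stem cell genes had a median of -0.63 (percentile 2.99; 7 members), with Lrig1 at -3.41, Bmi1 at -1.09 and Lgr5 at 0.85, and collagen and matrix genes -0.17 (percentile 3.0; 20 members), with Dcn at -1.37, Fn1 at -1.35 and Tnc at 0.80. Dcn, with 82.1% of its wild type counts in cluster 19, was at 0.62 once clusters of wild type E15.5 alone were left out. S phase genes had a median of -0.05, with 1 of 30, Usp1 at -1.17, beyond 1, and none of 31 G2 and M genes (0) passed 1 in size (median -0.13, Ccna2 -0.67 and Cdk1 -0.40). For p53 and apoptosis the median was -0.11 over 22 members (Mcl1 -2.19, Bbc3 0.90), and for hypoxia and glycolysis -0.01 over 20 (Pdk1 -0.96, Hk2 0.85). Immediate early genes, which rise during tissue dissociation, had a median of 0.13 (percentile 98.6), with 16 of 26 above 0 but Cebpb at -5.57, Hspb1 at -3.70, Jund at -1.82 and Klf2 at -1.75, and the median was -0.12 against the mean of the 3 wild type libraries. Haemoglobin genes took 0.511% of mesenchymal-like counts in wild type E15.5 and 0.365% in the knockout. Among sex-linked genes, Y-linked genes measured 83.8 and 105.9 CPM and Xist, transcribed from the inactive X, 295.2 and 253.5 CPM.

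As limits, 11 of the 20 named genes had a value over the shared clusters, and 8 of these kept a log2 ratio of at least 1 in size. Without clusters of wild type E15.5 alone, 11 of the 20 named genes met the size rule. The Dlx list median was -0.88 over the shared clusters.

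In epithelial-like cells the Dlx genes differed between the 2 E15.5 libraries in both directions. Relative to wild type E15.5, Dlx2 was lower (185.1 against 72.3 CPM, log2 ratio -1.36, -1.43 to -1.29), as were Dlx5 (121.1 against 58.5 CPM, -1.05, -1.13 to -0.97) and Dlx6 (-1.31). Dlx1 was higher (69.7 against 121.5 CPM, 0.80, 0.73 to 0.87), as were Dlx3 (0.84) and Dlx4 (0.57), and all of these directions held under each scaling tried. Over the 4 shared epithelial-like clusters with equal weights, Dlx1 stood at -0.04, Dlx3 at -0.52 and Dlx4 at -0.63. The list median was -0.24 (percentile 21.4). Dlx1 was counted in 30.6% of wild type and 56.4% of knockout epithelial-like cells and Dlx2 in 47.4% and 35.4%, at median depths of 5925.5 and 8516.5 counts, with the shares in endothelial-like and erythroid cells given above as background. Dlx2 was also lower in knockout endothelial-like cells (41 against 1 counts) and immune-like cells (48 against 2 counts).

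Named genes higher in the knockout epithelium were led by Gngt1 at 7.41 (6.07 to 9.92; 3 counts in wild type) and Slitrk1 at 6.997 (5.07 to 12.89; 1 count in wild type). Lrp1b, a large lipoprotein receptor, was at 4.92 (6.88 against 208.1 CPM), the adhesion receptor Adgrb3 at 4.79, the cell adhesion gene Cadm2 at 4.36 (9.88 against 202.7 CPM), Cilp at 3.95, the keratin Krt24 at 3.73, the glutamate receptor Grm8 at 3.69, the calcium-sensing receptor Casr at 3.61 and Lrrn3 at 3.58. For 8 of these genes most knockout counts lay in cluster 10, which held 1741 knockout and 76 wild type E15.5 cells. Gngt1 and Cilp had most of theirs in cluster 27 (565 and 21 cells). In the same epithelial-like cells Malat1, a nuclear RNA, measured 3885 CPM in wild type E15.5 and 14070.0 in the knockout. Cyp26c1, which degrades retinoic acid, was at least 244-fold lower in the knockout, with 1216 counts (26.1 CPM) in wild type E15.5, 17.7 and 28.9 CPM at E14.5 and E16.5, and 0 counts in the knockout. Serpinb2 was at least 588-fold lower, Cysrt1 at least 449.7-fold, Acer1, a ceramidase of the epidermis, at least 235-fold, Tuba8 at least 69.7-fold and Aadac at least 51.4-fold. Tgm3, an epidermal transglutaminase, with 1 knockout count, was at -9.09 (-14.98 to -7.19), Lypd5, with 2 knockout counts, at -8.71 (-12.08 to -7.17) and Fam25c at -8.69. All of these except Cyp26c1 had at least 90.2% of their wild type counts in cluster 26, led by epidermal genes such as Krt1 and Krt10, with 622 cells of wild type E15.5 and 0 of the knockout, so the tissue taken can set these folds too. Hotairm1 was at least 43.8-fold lower, with 68.8% of its wild type counts in cluster 23 (958 and 0 cells).

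FGF, Notch, Hedgehog and BMP lists were lower in the knockout epithelium. FGF components were below 0 in 14 of 17 members and at or below -1 in 10 (median -1.13, percentile 0), with the ligand Fgf9 at -2.57, Spry2 at -2.04, Etv1, an FGF-responsive transcription factor, at -1.79 and Spry1 at -1.57. Notch components were below 0 in 11 of 12 (median -1.35, percentile 0), with Nrarp at -3.84, Hey2 at -2.35, the ligand Jag1 at -1.75 and Notch1 at -1.47. Hedgehog components had 5 of 12 at or below -1 (median -0.94, percentile 0.09), with Gas1 at -3.64, Shh at -2.30 (156.9 against 31.9 CPM) and the receptors Ptch1 at -1.46 and Ptch2 at -1.04. In wild type, 69.0% of the Shh counts were in cluster 14, which held 845 wild type E15.5 and 129 knockout cells. BMP and TGF-beta components had 14 of 21 below 0 (median -0.36, percentile 2.03, or 2.68 without the trend on GC content and length), with Bmp5 at -2.07, Bmp7 at -1.82, Tgfbi at 1.94 and Serpine1 at 1.39. Over the shared epithelial-like clusters Tgfbi stood at -0.0222. Wnt components had 8 of 26 at or below -1 and 3 at or above 1 (median -0.20, percentile 12.9, within the random range), among them Dkk1 at -2.88, the receptor Lgr4 at -1.61 and Sfrp4 at 1.54.

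Cell cycle genes were lower as a group, with 30 of 30 S phase members (median -0.62, percentile 0; Usp1 -1.87, E2f8 -1.13, Clspn -0.98) and 31 of 31 G2 and M members below 0 (median -0.88, percentile 0; Ccna2 -1.47, Cdk1 -1.28, Mki67 -1.18). The class sums drew on different clusters, since cluster 10 held 1741 of 2922 knockout and 76 of 6168 wild type E15.5 cells and cluster 27 held 565 and 21, and Malat1 differed as given above. Of 6 ameloblast and enamel genes 4 were at or below -1 (median -1.90, percentile 0.06), with Sp6 at -3.07 (108.1 against 12.9 CPM) and Ambn at -1.50, while Odam, an ameloblast-secreted protein, was at 2.33 (88.6 against 445.0 CPM). All 9 odontoblast and bone genes were above 0 (median 0.93, percentile 99.99), with Runx2 at 1.71, Col1a2 at 1.45, Sparc at 1.38 and Ibsp at 0.94, and 13 of 20 collagen and matrix genes were (median 0.44, percentile 99.98), with Tnc at 1.38 but Dcn at -2.75. Col1a1, a marker of mesenchyme, was higher in the knockout in the 4 other classes measured, at 69.9 against 106.8 CPM in epithelial-like, 68.6 against 138.7 in endothelial-like, 88.7 against 156.9 in immune-like and 270.8 against 495.7 in erythroid cells. Hypoxia and glycolysis genes were below 0 in 14 of 19 (median -0.40, percentile 0.82), with Egln3 at -1.74, Ldha at -0.90 and Adm at 1.97.

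Lists that stood within the range of random lists were tooth transcription factors (median -0.34; 23 members; Barx1 -4.16 on 103 counts against 3, Msx1 1.97), distal jaw patterning (-0.48; 11 members; Nr2f2 -1.29, Hand2 0.99), enamel knot (-0.38; 14 members, 4 at or below -1 and 2 at or above 1; Cdkn1a -1.49), the Eya-Dach network (-0.03; 8 members; Eya1 1.28, Dach1 -0.62) and stem cell genes (-0.57; 8 members; Lrig1 -2.18, Sox21 -1.82, Bmi1 -1.32, Igfbp5 1.87). Medians of p53 and apoptosis genes (0.01; 21 members; Mcl1 -2.25, Pmaip1 -1.52, Bcl2 -1.43) and immediate early genes (-0.13; 26 members; Cebpb -6.06, Hspb1 -3.62) were in that range too. Haemoglobin genes took 0.358% and 0.141% of epithelial-like counts in wild type E15.5 and the knockout. Y-linked genes measured 54.3 and 118.6 CPM and Xist 290.3 and 146.1 CPM. As limits, TMM scaling moved the median of all genes to -0.14. Over shared clusters 13 of the 20 named genes had a value, and 8 of these met the size rule. Of the 20 genes, 12 met it without clusters of wild type E15.5 alone. Pmaip1 stood at 0.70 without those clusters.

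The wild type stages asked how expression changes from E14.5 to E16.5, and the mesenchyme gained Dlx expression. Dlx1 went from 5.24 CPM at E14.5 to 67.8 at E15.5 and 96.9 at E16.5, a log2 ratio of 4.21, and Dlx2 from 56.5 to 65.2 and 133.3 CPM, 1.24. Dlx3 (2.87), Dlx4 (3.77), Dlx5 (0.99) and Dlx6 (0.27) were higher too, and the list median was 2.06 at percentile 100. The stages lay in different clusters, with clusters 7 and 8 holding 2294 and 1352 of 5066 cells at E16.5 and 1 and 6 at E14.5. In cluster 9, papilla-like and present at both stages, the Dlx genes were lower at E16.5, with Dlx1 at 13.6 and 5.23 CPM, Dlx2 at 171.6 and 27.7 and Dlx5 at 125.8 and 55.3. Six1 moved the other way, by -0.41 (-0.54 to -0.28). The median of all genes was -0.22 in this comparison, and TMM scaling took it to -0.02.

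Named genes higher at E16.5 in the mesenchyme were Plac8 at 7.07 (1.20 against 162.4 CPM, 88.7% of counts in cluster 8), Ecel1 at 6.93, the enamel protein gene Enam at 5.38, Cidea at 5.14, Nmnat2, an NAD-synthesising enzyme, at 4.84, Shisa9 at 4.73, Fcrl6 at 4.69, Sall3 at 4.52, Lypd1 at 4.44 (7.37 against 160.0 CPM) and Pmch at 4.43. Genes lower at E16.5 were Gdf10, a TGF-beta family ligand, at -10.33 (-13.70 to -8.80; 89.9 CPM against 2 counts), Ebf2 at -9.75 (-13.11 to -8.21; 2 counts), the transcription factors Osr1 at -8.11 (119.8 against 0.419 CPM), Pax3 at -7.37 (159.0 against 0.95 CPM) and En1 at -6.64, Cbln4 at least 35.7-fold lower, Lrrtm4 at -7.30, Gpr22 at -7.15 (-13.04 to -5.25; 1 count), the Wnt co-receptor Lgr5 at -6.60 and Ostn at -5.99. Of these 10 genes all but Ostn had their largest part in cluster 1, which held 2257 cells at E14.5, 1059 at E15.5 and 0 at E16.5.

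Ameloblast and enamel genes were higher at E16.5 in mesenchymal-like cells, with 5 of 6 at or above 1 (median 3.68, percentile 100; Sp6 4.32, Ambn 3.04), and the epithelial keratin Krt14 went from 28.3 to 45.3 CPM in the same cells. Enamel knot genes had 4 of 11 at or above 1 (median 0.39, percentile 99.6), with Msx2 at 3.17, Bmp2 at 1.32 and Wnt10b at -2.64, and tooth transcription factors had a median of 0.20 (percentile 98.2, or 96.3 without the trend on GC content and length; 24 members), with Pitx1 at -4.53 and Tfap2b at -4.25. BMP and TGF-beta components had a median of 0.26 (percentile 99.2; 21 members), with Tgfbi at 2.36, Bambi, a decoy receptor, at 1.58, Grem1 at -2.43 and Serpine1 at -2.31. G2 and M genes were above 0 in 22 of 31 (median 0.23, percentile 98.7), with Ube2c at 0.89 and Cdk1 at 0.61. The Eya-Dach network was below 0 in 9 of 9 members (median -1.47, percentile 0.01), with Six2 at -4.41, Eya1 at -4.23, Eya4 at -3.46 and Six4 at -1.67. Collagen and matrix genes had 11 of 20 at or below -1 (median -1.05, percentile 0), with Tnc at -2.98, Postn at -2.27, Vcan at -1.54 and Col1a2 at -1.34. Without the trend on GC content and length the collagen median was -0.39 (percentile 0).

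Other stage medians in mesenchyme lay within the random range. These were distal jaw patterning (-0.59; 13 members; Gsc -4.26, Barx1 -2.65, Hand1 -1.98), Hedgehog (-0.11; 12 members; Cdon -3.23, Gas1 -1.94, Boc -1.94, Hhip 1.58), Wnt (-0.02; 28 members; Rspo4 4.26, Wnt10a 4.15, Wnt6 3.93), FGF (-0.56; 17 members; Etv1 -1.75, Spry1 -1.49, Dusp6 -1.47) and Notch (-0.62; 13 members; Hey2 -3.03, Dll1 3.02, Notch1 -2.14). Odontoblast and bone genes had a median of 0.19 (14 members; Bglap 4.74, Dmp1 2.75, Spp1 -1.95), stem cell genes -0.64 (8 members; Lrig1 -1.91, Bmi1 -0.66, Pitx2 0.65), and S phase genes -0.08 (30 members; Slbp -0.74). The medians were -0.18 for p53 and apoptosis (22 members; Pmaip1 -2.16, Bcl2l11 -1.84), 0.10 for immediate early genes (26 members; Klf4 -1.32) and -0.08 for hypoxia and glycolysis (20 members; Egln3 -1.93, Slc2a1 -1.23). Haemoglobin genes took 0.306% of counts at E14.5 and 0.426% at E16.5. Y-linked genes measured 41.7 CPM at E14.5 and 0.307 at E16.5 and Xist 377.0 and 266.3 CPM, so the mix of embryo sexes differed between these stages. Long transcripts were lower in the E16.5 library across all classes. Ranked anew without the trend on length and GC content, 18 of the 20 genes named here were named again.

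In the wild type epithelium, the genes named as higher at E16.5 included those of enamel and dentine matrix. Amelx, the enamel matrix protein amelogenin, went from 0 counts at E14.5 to 51.8 CPM, at least 507.5-fold higher, with 87.0% of its counts in cluster 12. The regulator Sim2 was at least 235-fold higher, the dentine matrix gene Dspp at least 196-fold, Gpr174 at least 27.3-fold and Coro6 at least 25.6-fold. Ambn was at 8.16 (0.919 against 268.7 CPM), Spns3 at 7.50 (5.96 to 10.87; 2 counts at E14.5), Epyc at 6.67 (4.76 to 12.56; 1 count at E14.5), the collagen gene Col22a1 at 6.55 and Scrn1 at 6.37. On the other side, Fgf4, a ligand of the enamel knot, was at least 136-fold lower and Krt6b at least 73.4-fold. Fgf15 was at -9.29 (-15.18 to -7.39; 1 count at E16.5), Dmrt2 at -8.42 (-11.79 to -6.88; 2 counts), Wfdc10 at -7.64 (-13.54 to -5.73; 1 count), Oxtr, the oxytocin receptor, at -7.05 (-10.42 to -5.50; 2 counts) and the Wnt inhibitor Dkk4 at -6.71 (-9.22 to -5.36; 3 counts). Otx1 was at -6.55, the chemokine Cxcl2 at -6.01 and Ltb at -5.90. Fgf4, Fgf15, Wfdc10, Dkk4, Cxcl2 and Ltb had most of their E14.5 counts in cluster 14, which held 329 of 2087 epithelial-like cells at E14.5 and 259 of 5321 at E16.5, and Dmrt2, Oxtr and Otx1 in cluster 17. Six1 was at 0.32 (-0.04 to 0.71), a change not detectable at this depth.

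All 6 Dlx genes were higher at E16.5 in the epithelium (median 2.16, percentile 100), with Dlx6 at 3.95, Dlx4 at 2.81, Dlx5 at 2.35 and Dlx1 at 0.95. Odontoblast and bone genes had 8 of 14 at or above 1 (median 2.47, percentile 100), such as Ifitm5 at 3.14 and Ibsp at 3.04, with Dmp1 at 6.35 (4.44 to 12.25) on 1 count at E14.5. These 3 genes were among the leading genes of the osteogenic cluster 18, with 3 cells at E14.5 and 1227 at E16.5, and Col1a1 in epithelial-like cells went from 62.7 to 119.6 CPM. For 9 ameloblast and enamel genes the median was 0.84 (percentile 99.95), with the enamel protease Mmp20 at 5.89 (3.97 to 11.78) on 1 count at E14.5, and Sp6 at 1.20. BMP and TGF-beta components had a median of 0.44 (percentile 100; 21 members, 13 above 0), from Bambi at 2.35 and Bmp5 at 2.34 to Serpine1 at -3.03 and Bmp3 at -2.60.

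Lists lower at E16.5 in the epithelium included the Eya-Dach network (9 of 9 below 0, median -1.39, percentile 0.02; Eya4 -3.29, Six4 -2.37, Eya1 -1.85, Dach2 -1.39), enamel knot (11 of 14 below 0 and 7 at or below -1, median -0.78, percentile 0.08; Wnt10b -2.45 but Msx2 2.98) and Wnt (21 of 28 below 0, median -0.76, percentile 0.06; Lgr5 -3.73, Lgr4 -2.81, Dkk1 4.05, and Rspo4 5.46, 3.53 to 11.36, on 1 count at E14.5). Tooth transcription factors had 9 of 24 at or below -1 (median -0.66, percentile 0.22), with Barx1 at -4.50, Lhx8 at -2.99, Lhx6 at 3.28, and Tfap2b at least 104-fold lower. FGF components were below 0 in 14 of 17 (median -0.60, percentile 0.60; Etv5 -1.17, Spry2 -1.16), and collagen and matrix genes in 14 of 20 (median -0.59, percentile 0.24; Postn -3.17, Lum 1.83). Without the trend on GC content and length these 2 medians were -0.26 (percentile 3.52) and -0.05 (percentile 32.9), within the random range. Cell cycle genes were again below 0, in 30 of 30 S phase members (median -0.64, percentile 0; Uhrf1 -1.41, E2f8 -1.33) and 30 of 31 G2 and M members (median -0.41, percentile 0.05; Mki67 -1.12, Top2a -0.91). The stages drew on different clusters here as well, since cluster 12 held 2 cells at E14.5 and 1797 at E16.5, cluster 16 held 4 and 923, cluster 25 held 2 and 576 and cluster 17 held 601 and 0. Hypoxia and glycolysis genes were below 0 in 19 of 20 (median -0.54, percentile 0.12; Egln3 -3.30, Pgk1 -1.35, Slc2a1 -1.32).

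Within the random range were distal jaw patterning (median -0.67; 11 members; Edn1 -2.49, Satb2 1.55), Hedgehog (-0.58; 12 members; Gas1 -1.89, Cdon -1.13), Notch (-0.12; 13 members; Heyl 2.85, Jag1 -1.62), stem cell genes (0.08; 8 members; Sox21 3.55, Lrig1 -1.92), p53 and apoptosis (-0.22; 21 members; Pmaip1 -1.14, Cdkn1a 0.98) and immediate early genes (0.04; 26 members; Ier3 -1.08, Hspb1 0.96). Haemoglobin genes took 0.137% and 0.252% of counts at E14.5 and E16.5, Y-linked genes measured 40.2 and 0.117 CPM and Xist 259.8 and 202.0 CPM. As limits, the median of all genes was -0.18 here and 0.12 after TMM scaling, and 16 of the 20 named genes met the size rule without the 4 epithelial-like clusters led by markers of other classes, cluster 12 among them.

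**Figure D4:**
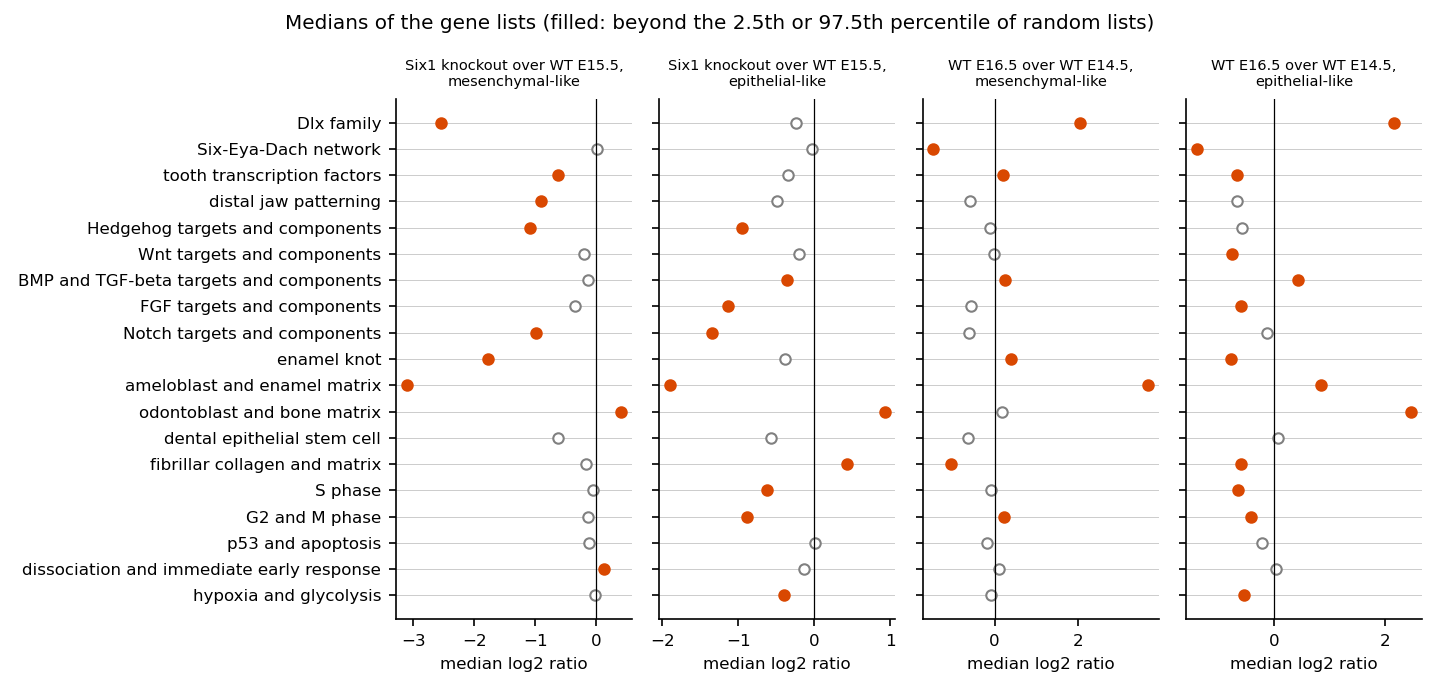
Median log2 ratio (horizontal axes) of the 19 lists other than haemoglobin and sex-linked genes (vertical axis) in the 4 comparisons, with filled points where the median lay in the outer 2.5% of random lists on either side. The Dlx family stood at -2.55 in the knockout mesenchyme and at 2.06 and 2.16 in the stage comparisons of mesenchyme and epithelium.

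Whether the knockout lay nearer an earlier stage was read from genes that change with stage in wild type. Wild type E15.5 both helped to choose these genes and was the reference of the knockout ratio. Cluster composition also differed between the libraries, so the medians below cannot place the stage of the knockout. In mesenchyme the 227 genes higher with stage had a median log2 ratio of -0.74 between knockout and wild type E15.5, with 178 below 0 and 49 above. The 656 genes lower with stage had a median of 0.00, with 328 on each side. With TMM and median-of-ratios factors the rising genes stood at -0.40 and -0.35, the falling genes at 0.21 and 0.22 and all genes at -0.02 and 0.00. In epithelium the medians were -0.18 for 292 rising genes and -0.07 for 588 falling genes. Across all genes, which are not independent replicates, the knockout ratio and the stage ratio had Spearman's rho of 0.0456 and Pearson's r of -0.0642 in mesenchyme (10532 genes) and 0.119 and 0.0242 in epithelium (10377 genes).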

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

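Tests of the GC trend on the genes lower in 4 classes, of the knockout's cluster composition, of cluster 9 and of the position between E14.5 and E15.5 were chosen after the results they address had been seen, while those on shared clusters, matched genes and free RNA were written before.

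Dlx1, Dlx3 and Dlx4 stood out because the knockout was below wild type E15.5 in mesenchymal-like cells and above it in epithelial-like cells. The log2 ratio in mesenchyme minus that in epithelium was -5.21 for Dlx1 (-4.41 and 0.80), -3.35 for Dlx3 (-2.51 and 0.84) and -3.16 for Dlx4 (-2.58 and 0.57), while over the shared epithelial-like clusters Dlx1 was at -0.04, Dlx3 at -0.52 and Dlx4 at -0.63. Between wild type E14.5 and E16.5, the median of 3 lists was above 0 in mesenchyme and below 0 in epithelium. The difference was 0.87 for tooth transcription factors (0.20 and -0.66, the former at percentile 96.3 without the GC and length trend), 1.17 for enamel knot genes (0.39 and -0.78) and 0.64 for G2 and M genes (0.23 and -0.41). None of these differences between the classes was tested, since each value rests on 1 library per group.

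Lower Dlx1 and Dlx2 in the knockout mesenchyme was weighed against cell composition, level within cells, stage and sequence bias. Wild type E15.5 levels per cluster at the knockout's composition gave log2 ratios of -3.45 for Dlx1 and -1.72 for Dlx2 of the observed -4.41 and -3.08. Fewer cells of the clusters rich in these genes may thus account for the larger part, but its size is uncertain. Cluster 0 held 4048 knockout cells but only 93 of wild type E15.5. Its wild type level was 3.28 CPM for Dlx1 (0.0832 to 18.3) and 26.3 for Dlx2 (11.3 to 51.8), not set apart from immune-like cells. No interval was computed for the expected ratios. A lower level in the cells grouped in cluster 9 is argued against, since the log2 ratio there was 1.01 for Dlx1 and 1.29 for Dlx2. This says little about most cells that carried the genes in wild type E15.5. Of 1246 mesenchymal-like cells with a Dlx1 count, 740 lay in cluster 15, with 1 knockout cell, and 34 in cluster 9. Knockout cells that lost papilla genes may also have left cluster 9. GC or length bias is argued against, since both genes lay at percentile 0 of the 200 genes nearest in GC content, length and expression. Knockout levels over the class were 0.607 and 0.137 times those of E14.5, below a position between E14.5 and E15.5. Cluster composition can set these class levels, so the position is not decided. Within cluster 9 the knockout's Dlx2 lay between the levels of E14.5 and E15.5, and its Dlx1 above both. The mean over shared clusters (-1.40 and -1.86) decided nothing, because outside cluster 9 no wild type level exceeded that of immune-like cells by more than the counting intervals, and whether cells were lost or clusters were named apart after loss of their markers stays open, as does Six1 loss itself in 1 library.

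A further pattern was 264 of 7005 genes lower by at least 1 on the log2 scale in the knockout in mesenchymal-like, epithelial-like, endothelial-like and immune-like cells alike, where 1.03 would be expected if the classes were independent, against 5 genes higher in all 4. The same count was 242 for wild type E16.5 over E15.5, 60 for E16.5 over E14.5 and 20 for E14.5 over E15.5, so wild type libraries also differed in this way. In mesenchymal-like cells the median of the 264 genes in the knockout was -1.59 over wild type E14.5 and -1.47 over wild type E16.5. Dlx2, Bmi1, Cebpb, Gas1, Jund and Mcl1 were among the 264 genes, together with Gnas and Rac1, but 0 of the 20 named genes of either knockout comparison. That 0 says little, since only 4 named genes in mesenchyme and 1 in epithelium had enough counts in endothelial-like or immune-like cells. The genes' median level in endothelial-like cells was 0.838 of that in the higher of the main classes. This argues against free RNA from the most abundant cells only for the genes as chosen. They needed at least 30 counts in endothelial-like and in immune-like cells, which favoured such a ratio. Without the GC trend the genes' median was -1.37 (upper quartile -1.09) in the class where it lay nearest 0. That outcome was nearly fixed, since the genes were chosen at or below -1 and the trend was small. Their median GC content was 50.8%, and all mesenchymal-like genes from 50 to 55% had a median of -0.09. It shows only that the average GC trend did not take up their drop. How far GC bias contributed is not settled, as 75.8% of the genes then stayed at or below -1 in all 4 classes. Free RNA stays open for 14 genes with a lowest class under 0.1 of the highest. Examples were Dlx2 (9.20 CPM in endothelial-like against 185.1 in epithelial-like cells) and Cpa3 (8.07 against 8989 in immune-like cells). Six1 loss in every class cannot be told apart from another difference between the 2 single libraries (median -1.64 in mesenchyme).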

How the results depend on the processing

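No paired analysis was possible because each group was 1 library. The alternatives on shared clusters, the GC and length trend, endothelial-like and immune-like cells, doublet scores removed everywhere, clusters of wild type E15.5 alone and the 4 epithelial-like clusters were chosen after the data had been seen. All 20 named genes of each comparison kept their sign under the alternatives fixed in advance, where these gave a value. They were chosen for the largest ratios, so this outcome was nearly fixed. Against the mean of the 3 wild type libraries the naming rule itself fixed it. The Dlx list stayed below 0 in the knockout mesenchyme and above 0 in both stage comparisons under every alternative that gave it a median. Subtraction of the change in endothelial-like and immune-like cells left too few Dlx genes for a median. For each value below that moved or reversed, the cause was not tested, except that thinning and subtraction leave fewer genes with enough counts. Depth limits the low ratios, since 0 counts of a gene in a class allow up to 3.

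With every cell thinned to 2000 counts, 8 of the 20 named genes met the size rule in the knockout mesenchyme, 11 in the knockout epithelium and 6 in the stage epithelium. The Dlx median was then -2.92 in the knockout mesenchyme and 2.70 and 2.08 in the stage comparisons of mesenchyme and epithelium, and Six1 measured 45 CPM in E15.5 mesenchyme and 6.18 and 2.76 CPM in E15.5 and E16.5 epithelium. Means over cells gave Dlx medians of -3.05 in the knockout mesenchyme and 2.79 in the stage mesenchyme. Against the mean of the 3 wild type libraries the Dlx median in the knockout epithelium was -0.41, Gsc in mesenchyme reversed to 0.37 and the immediate early median to -0.12.

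Over clusters shared by both E15.5 libraries, 8 genes in mesenchyme and 8 in epithelium met the rule, of 11 and 13 with a value. The Dlx median was -0.88 in mesenchyme and -0.78 in epithelium, and Pirt (-0.0039) and Dcn (0.81) in mesenchyme and Tgfbi (-0.0222) and Pmaip1 (0.22) in epithelium reversed. Dlx1 (-0.04), Dlx3 (-0.52) and Dlx4 (-0.63), which were above 0 in the epithelium by less than 1, turned below 0. After subtraction of the change in endothelial-like and immune-like cells, 3 genes in mesenchyme and 1 in epithelium met the rule, of 4 and 1 with a value. Reversed were Dlx2 (0.71), Sfrp2 (0.22), Bmi1 (0.13) and Fbn1 (0.20) in mesenchyme and Dlx2 (2.43) and Lgr4 (0.62) in epithelium. The change subtracted for Dlx2 rested on 41 against 1 and 48 against 2 counts of background, so its turn tests nothing. Without clusters of wild type E15.5 alone, 11 and 12 genes met the rule, the Dlx medians were -2.34 and -0.43, and Dcn (0.62) in mesenchyme and Pmaip1 (0.70) in epithelium reversed. The Dlx median of the stage epithelium was 2.06 without the GC and length trend and 1.88 without the 4 epithelial-like clusters.

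TMM factors gave Dlx medians of 2.25 in the stage mesenchyme and 2.46 in the stage epithelium, and medians of -0.40 and 0.21 for rising and falling genes in the knockout mesenchyme and -0.0611 for rising genes in the epithelium. Median-of-ratios factors gave Dlx medians of 2.31 and 2.41, and medians of rising and falling genes of -0.35 and 0.22 in mesenchyme and -0.0598 and -0.0264 in epithelium. With a minimum of 30 counts, rho was 0.0171 and r -0.0828 in mesenchyme, with medians of -0.80 for rising and 0.0625 for falling genes. In epithelium rho was then 0.0948, r 0.0079 and the median of falling genes 0.0062.

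Without doublet removal, mesenchymal-like shares were 64.6% at E14.5, 48.5% at E15.5 and 63.7% in the knockout, epithelial-like shares 39.9% at E15.5 and 27.9% in the knockout, and Six1 in E15.5 epithelium 6.31 CPM. A minimum of 1000 genes gave mesenchymal-like shares of 42.4% at E16.5 and 67.5% in the knockout, and epithelial-like shares of 19.5%, 42.8%, 45.5% and 29.3% in the order of the libraries. Components centred per library gave epithelial-like shares of 13.7%, 41.9%, 31.96% and 23.6%, papilla-like shares of 13.5%, 11.3%, 46.55% and 0.229%, follicle-like shares of 30.6% at E14.5, 24.1% at E15.5 and 45.8% in the knockout, and Six1 at 2.57 CPM in E16.5 epithelium.

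Leiden resolution 0.5 gave papilla-like shares of 0.0906%, 7.91%, 31.4% and 0.0422% and follicle-like shares of 45.8%, 30.3%, 1.01% and 13.03% in the same order. Resolution 2.0 gave papilla-like shares of 6.75%, 9.88% and 46.4% in the wild type stages, follicle-like shares of 34.04%, 15.6%, 18.8% and 45.4%, a mesenchymal-like share of 47.3% and Six1 at 18.0 CPM at E16.5, and a stage Dlx median of 1.99 in mesenchyme. A mitochondrial limit of 10%, 5% of doublet scores removed everywhere and totals without mitochondrial, ribosomal and haemoglobin genes moved none (0) of the 24, 4 and 9 main results run with them. Without a minimum count, the 8 main results could not move, since this only relaxes the rule. Ranked anew in that setting, 8 and 12 of the 20 named genes of the knockout mesenchyme and epithelium were named again. For stage, 14 and 19 were. Against the mean of the 3 wild type libraries, 10 and 11 of the knockout genes were. Of 76 list medians in the 4 comparisons, 40 lay in the outer 2.5% of random lists on either side. TMM and median-of-ratios factors shift all genes of a library alike, so they could hardly change a percentile. Under either, 40 of these list medians stayed there, and 37 did with means over cells. Without the GC and length trend 35 stayed. Those that left were distal jaw patterning (-0.10) in the knockout mesenchyme, BMP and TGF-beta (-0.28) in the knockout epithelium, tooth transcription factors (0.24) in the stage mesenchyme, and FGF (-0.26) and collagen and matrix (-0.05) in the stage epithelium. Distal jaw patterning (-0.49), Notch (-0.53) and Wnt (0.29) in the stage mesenchyme and distal jaw patterning (-0.79) in the stage epithelium entered.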

Other observations

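The test of length bias across classes was chosen after the trend had been seen, and that on the named stage genes was written before.

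Clusters of the wild type mesenchyme differed in their Dlx genes at a single stage. At E16.5 Dlx1 measured 208.8 CPM in the papilla-like cluster 7 and 62.4 in the papilla-like cluster 8, and Dlx2 201.5 and 142.8 CPM. Dlx1 was at 5.23 CPM in cluster 9 at that stage and at 6.56 in follicle-like cells, while Six1 measured 12.4 CPM in cluster 7, 11.2 in cluster 8, 46.4 in cluster 9 and 45.3 in follicle-like cells. At E15.5 cluster 5 held 88.9 CPM of Six1 and 6.18 of Dlx1, and cluster 15 held 19.5 of Six1 and 384.5 of Dlx1. Both genes were sparse in clusters 1 and 19 of that library, with Six1 counted in 6.52% and 2.17% of cells and Dlx1 in 1.70% and 2.70%. Chondrogenic cells of E14.5 held Six1 at 42.8 CPM on 247 counts. Malat1, a nuclear RNA, measured 3885 CPM in epithelial-like cells of wild type E15.5 and 14070.0 in those of the knockout, and 3252 and 6395 CPM in mesenchymal-like cells.

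Long transcripts were lower in the wild type E16.5 library. In mesenchymal-like cells the median log2 ratio of E16.5 over E15.5 was -0.88 for 2786 genes with transcripts over 5000 nucleotides and 0.46 for 362 genes under 1000. The trend was as strong in endothelial-like cells (Spearman's rho -0.579 across genes) and present in immune-like cells (-0.465), so a length bias of that library may underlie it, and a stage effect shared by all classes stays open. Of the genes named for stage, 40 of 40 kept a log2 ratio of at least 1 in size without the trend on length and GC content. They were chosen for far larger ratios, so this outcome was nearly fixed. Ranked anew without the trend, 18 of the 20 named in mesenchyme and 20 of 20 in epithelium were named again. For E16.5 over E14.5 in mesenchyme, the medians were 0.38 under 1000 and -0.64 over 5000 nucleotides. These were small beside the named ratios, so the new ranking was nearly fixed too. The average trend was too small to give such ratios, and a bias on single genes was not tested.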
